A study of Homo sapiens with 12 samples.

How the data were processed

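The series holds RNA-seq and CUT&Tag samples of H9 human embryonic stem cells. RNA-seq libraries were made from small numbers of cells with a kit for full-length amplification of mRNA, per the labels' protocols. Per the submitters' processing notes, the genome build was hg38 and the tools included Bowtie2 2.5.0, featureCounts, bedtools, MACS2 2.2.7.1, ChIPseeker and deepTools. The notes give these tools no role, and the RNA-seq aligner, the use of strand and the treatment of reads with several alignments are not given in the sources used here. Labels and columns of 6 RNA-seq libraries matched, 2 in each of 3 groups. The CUT&Tag samples had no columns in the table analysed and were not analysed here.

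The deposited table gave gene counts per library in the layout of featureCounts, with coordinates and gene length per row, per the file headers. These counts were whole numbers, not normalized by the authors. Beside them the authors deposited FPKM values, the count scaled by gene length and by the library's total. The table had 45433 lines after its header. Of its genes 45429 had complete counts and FPKM; 2 genes had broken records and were left out, one of them ANK2. Counts in the rows left out came to 721 to 910 per library, judged from the totals that the FPKM imply. Gene symbols came from the table; 45416 Ensembl identifiers were found in the gene name table, and 30346 rows had a biotype in RefSeq for GRCh38.p14.

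Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, with robust dispersion, TMM factors and the filterByExpr filter. One fit held all 6 libraries in 3 groups, which shared one estimate of the spread, because 2 libraries per group leave 3 residual degrees of freedom. The fit had 19149 genes, a common biological coefficient of variation of 0.230 and a median of 12.0 prior degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. CPM values are TMM-scaled, errors of log2 fold changes are standard errors from the F statistic, and errors of CPM are standard deviations over 2 libraries. Exact permutation of 2 against 2 libraries cannot give a p under 0.333. Library composition was described, and no other test of it was run.

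Gene lists on fuel metabolism, lipids, pluripotency, lineage and other cell types, stress responses, cell cycle, chromatin enzymes, histones and ribosomal proteins were fixed before the data were examined. Of 34 lists, 33 had at least 5 tested members. They were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, from limma 3.58.1 and edgeR. With an estimated correlation camera takes the 3 residual degrees of freedom, so its p can rise without correlation between members. Adjusted p of lists were taken over the 33 lists. The comparisons, the tests, the alternatives and the rule for naming genes were also fixed before the data were examined. The rule took, for the 2 main comparisons, up to 8 called protein-coding genes each way with a mean of at least 10 CPM and no overlap between the groups. It added the 3 members with the smallest p of each list called and of 4 lists on fatty acids and primed pluripotency, and CPT1A, HADHA, HADHB, ACAA2, FASN, POU5F1, SOX2 and NANOG. For CGA-TMZ against Vehide it took up to 5 each way, and XIST and genes on Y were never named. For genes moved back it took those called in both comparisons with opposite sign at a mean of at least 10 CPM.

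The alternatives were size factors by the median of ratios, upper quartile factors, a library size without mitochondrially encoded and ribosomal protein genes, the DESeq2 1.42.0 Wald test, limma-voom, no low-count filter, a mean of at least 10 CPM, the groups compared alone, the replicate number as a block, a minimum of a 2-fold change, limma on log2 of the deposited FPKM plus 1 or 0.1, and each library left out in turn. Where a group then held 1 library, that library was assumed to vary like the other groups. A fit with each library's trend on gene length removed, list tests on the groups compared alone, and a count of genes moved back with a different CGA library in each comparison, were chosen after seeing the data. Rescaling by median-of-ratios or upper quartile factors moved the median log2 fold change of a comparison by 0.08 at most. It left the share of higher against lower calls within 10 percentage points of the main one.

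The test was tested on simulated data with 50 genes changed at each of 4 fold changes per comparison. In CGA against Vehide, with 18386 genes in the fit, it recovered 16% of 50 genes changed 1.5-fold, 54% changed 2-fold, 92% changed 4-fold and 98% changed 8-fold, with 6 false calls. In CGA-TMZ against CGA, with 18383 genes, these shares were 14%, 64%, 94% and 98%, with 12 false calls. In CGA-TMZ against Vehide, with 18335 genes, they were 20%, 66%, 88% and 98%, with 19 false calls. A simulated trend on gene length in the CGA libraries gave 1418 calls among 18068 genes before the length correction and 4 after it. No 2 libraries agreed within sampling noise: the chi-square per degree of freedom between replicates was 25.8 in Vehide, 23.9 in CGA and 89.6 in CGA-TMZ. The labels mention no molecular identifiers, so counts may include amplification copies. Figures were drawn with matplotlib 3.10.9.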

Results

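Gene expression was measured by RNA-seq in H9 cells, an established line of human embryonic stem cells. The cells received chlorogenic acid, a plant polyphenol whose effect on fatty acid metabolism is the stated subject of the series. The groups were Vehide (the label's spelling, taken here as the vehicle), CGA (chlorogenic acid) and CGA-TMZ (chlorogenic acid with an addition the labels abbreviate as TMZ), with 2 libraries each. Total counts per library were 66029503 and 53014469 in Vehide, 49575999 and 50491716 in CGA, and 53391934 and 56064174 in CGA-TMZ. Mitochondrially encoded RNA took 3.91% to 5.65% of counts, and ribosomal protein genes took 5.86% in CGA replicate 1 to 7.74% in CGA-TMZ replicate 2. The CGA-TMZ libraries differed most between replicates, with a chi-square per degree of freedom of 89.6 against 25.8 in Vehide and 23.9 in CGA. Per gene the contrast was milder: the SD of the log2 difference between replicates was 0.794 in CGA-TMZ, 0.707 in Vehide and 0.696 in CGA. The labels number the libraries but do not say whether they came from separate cultures, so p-values measure only the spread between these samples, which may be technical. CUT&Tag samples of the series were not analysed here.

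The first comparison, CGA against Vehide, asked what chlorogenic acid changed. In the CGA libraries 5 genes rose and 3 fell among 19149 tested (edgeR, adjusted p < 0.05). Of the genes at 10 CPM or more, SLC29A1 rose from 51.5 ± 13.4 to 131 ± 1.34 CPM (SD, n = 2 each). SLC29A1 encodes the equilibrative nucleoside transporter ENT1, and its log2 fold change was 1.34 ± 0.18 (SE, adjusted p = 0.0193). USB1, which encodes an exonuclease that trims U6 small nuclear RNA, rose from 10.8 ± 1.56 to 29.7 ± 0.386 CPM. Its log2 fold change was 1.46 ± 0.21 (SE, adjusted p = 0.0197). NCSTN, which encodes the gamma-secretase subunit nicastrin, rose from 11.6 ± 1.39 to 29.3 ± 2.44 CPM, a log2 fold change of 1.34 ± 0.22 (SE, adjusted p = 0.0485). In hg38 coordinates of the deposited table, SLC29A1 spans 44219553 to 44234142 on chromosome 6. USB1 spans 57999546 to 58021618 on chromosome 16, and NCSTN spans 160343294 to 160358952 on chromosome 1. Without Vehide replicate 2 the adjusted p was 0.153 for SLC29A1 and 0.170 for USB1, and NCSTN lost its call without Vehide replicate 1, Vehide replicate 2 or CGA replicate 1 (adjusted p up to 0.353).

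The other 5 called genes had mean levels under 10 CPM and are named after their values were seen. BFAR, which encodes an apoptosis regulator, fell from 527 and 241 counts in Vehide to 51 in each CGA library (log2 fold change -2.68, adjusted p = 0.00654). DHRS1, which encodes a short-chain dehydrogenase, fell from 90 and 79 counts to 6 and 9 (log2 fold change -3.28). The pseudogene MTX1P1 fell from 319 and 662 counts to 5 in each library (log2 fold change -6.46). Its row is uncertain, because reads can be shared with the parent gene MTX1, which held 1865 to 2554 counts in the 6 libraries. SLC39A3, a zinc transporter gene, rose from 45 and 55 counts to 225 and 202 (log2 fold change 2.26). EEF1D, a translation elongation factor gene, rose from 6 and 2 counts to 80 and 120. Its row is uncertain too, with a mean of 52.3 counts over the 6 libraries for a gene that cells in general use in translation. BFAR and MTX1P1 passed in all 6 fits that left out a library. Without Vehide replicate 2 the calls of DHRS1, SLC39A3 and EEF1D were lost, without CGA replicate 1 those of DHRS1 and SLC39A3, and without Vehide replicate 1 that of SLC39A3 (adjusted p up to 0.0824, 0.0856 and 0.153 for DHRS1, SLC39A3 and EEF1D).

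Genes of glycolysis lay higher with CGA: 16 of 22 members had estimates above 0, with a median log2 fold change of 0.39, and the list passed the competitive test (camera, adjusted p = 8.49e-04). The call did not hold with an estimated correlation between genes (adjusted p = 0.994). No member passed the edgeR test over all genes (8 at an unadjusted p under 0.05), while 6 rose when adjusted over the list alone. GAPDH was at 614 ± 139 CPM in Vehide and 1153 ± 124 in CGA (log2 fold change 0.91 ± 0.20, SE, adjusted p = 0.119). PGAM1, which encodes phosphoglycerate mutase, was at 326 ± 34.9 and 516 ± 32.7 CPM (adjusted p = 0.146). The glucose transporter gene SLC2A1 was at 40.0 ± 5.57 and 59.9 ± 12.3 CPM (adjusted p = 0.278). GAPDH has many processed pseudogenes, so its level carries the uncertainty of shared reads.

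Cholesterol synthesis genes lay lower with CGA, with 17 of 23 estimates below 0 and a median of -0.19 (camera, adjusted p = 0.0166). With an estimated correlation the adjusted p was 0.994 (camera, unadjusted p = 0.0421). That estimate was -0.0126, below the preset 0.01, so correlation between members did not raise the p. The test with an estimated correlation rests on 3 residual degrees of freedom. HMGCS1, the cytosolic HMG-CoA synthase, was at 136 ± 10.8 CPM in Vehide and 73.3 ± 4.81 in CGA (log2 fold change -0.89 ± 0.18, SE, adjusted p = 0.0963). It was the 1 member that fell when adjusted over the list alone. DHCR7, which acts at the last step of the pathway, went the other way with a log2 fold change of 0.64 (adjusted p = 0.326). The list's adjusted p was 0.319 without Vehide replicate 1 and 0.267 without CGA replicate 1.

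Cytosolic ribosomal protein genes and nuclear-encoded oxidative phosphorylation genes also passed as lower lists (camera, adjusted p = 1.21e-10 and 1.63e-04; adjusted p = 0.994 for both with an estimated correlation). Estimates were below 0 in 69 of 82 ribosomal protein genes and in 53 of 69 oxidative phosphorylation genes, with medians of -0.22 and -0.21, and 0 members of either passed the edgeR test, over all genes or adjusted over the list alone, with 9 ribosomal members below 0 and, for oxidative phosphorylation, 4 above and 6 below 0 at an unadjusted p under 0.05. Both calls were lost without CGA replicate 1, at adjusted p of 0.195 and 0.267. Among the ribosomal members, RPL22L1 had a log2 fold change of -0.43 (adjusted p = 0.276) and RPL26 one of -0.35 (adjusted p = 0.410). RPS18 had -2.48 (adjusted p = 0.278), but -0.87 without Vehide replicate 1, which held the highest of its 8 to 95 counts. It lies in a stretch of chromosome 6 where 80% of protein-coding rows held under 20 counts. The oxidative phosphorylation members with the smallest p did not all go with their list. ATP5F1B, the beta subunit of ATP synthase, had a log2 fold change of 0.57 (adjusted p = 0.266). CYC1, cytochrome c1, had 0.47 (adjusted p = 0.282), and UQCRB, a complex III subunit, had -0.41 (adjusted p = 0.361).

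No fatty acid list passed the test. In mitochondrial beta-oxidation 0 of 28 members passed the edgeR test, with 1 at an unadjusted p under 0.05 and a median log2 fold change of 0.04 (camera, adjusted p = 0.988). HADHA and HADHB, the subunits of the trifunctional protein, had log2 fold changes of 0.09 ± 0.15 and 0.03 ± 0.13 (SE). ACAA2, a thiolase of the same pathway, had 0.06 ± 0.14. CPT1A, the carnitine palmitoyltransferase at the entry of the pathway, had -0.42 ± 0.30 at 1.98 ± 0.187 CPM in CGA. Members with the smallest p were ACAD9 (0.72, adjusted p = 0.521), CPT2 (0.51, adjusted p = 0.630) and DECR1 (-0.24, adjusted p = 0.646). In synthesis, elongation and desaturation, 2 of 28 members rose when adjusted over the list alone and none over all genes (camera, adjusted p = 0.140, unadjusted p = 0.0296), with 18 estimates above 0 and a mean log2 fold change of 0.26. In the fit of the CGA and Vehide libraries alone 3 members rose. SLC25A1, the mitochondrial citrate carrier, was at 14.7 ± 3.02 CPM in Vehide and 35.6 ± 1.64 in CGA (log2 fold change 1.27 ± 0.28, SE, adjusted p = 0.156). ELOVL1 had a log2 fold change of 1.08 (adjusted p = 0.215) and FADS3 had 1.34 (adjusted p = 0.278), while FASN had 0.05 (adjusted p = 0.981). In uptake, storage and lipolysis 0 of 26 members passed the edgeR test, with 3 above and 3 below 0 at an unadjusted p under 0.05 (camera, adjusted p = 0.988). PLIN3, a lipid droplet coat gene, had 0.81 (adjusted p = 0.306), LPIN1 had -0.62 (adjusted p = 0.333) and G0S2 had -1.05 (adjusted p = 0.377).

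The primed pluripotency list did not move as a group (camera, adjusted p = 0.646), and 1 of 29 members rose when adjusted over the list alone. NANOG was at 34.6 ± 1.35 CPM in Vehide and 54.2 ± 2.46 in CGA (log2 fold change 0.65 ± 0.15, SE, adjusted p = 0.134). ZFP42 had 0.43 (adjusted p = 0.270), OTX2 had 0.40 (adjusted p = 0.320) and SOX2 had -0.32 (adjusted p = 0.650). POU5F1 had 0.51 (adjusted p = 0.553), at only 323 to 547 counts per library, inside the same poorly counted stretch of chromosome 6 as RPS18. POU5F1B, a gene of like sequence on chromosome 8, held more counts than POU5F1 in each library (481 to 1155). It is named after its values were seen, and sharing of reads between the rows of POU5F1 and POU5F1B was not tested. Markers of trophoblast and amnion, another fate open to these cells, had a median of 0.49 over 13 tested members without passing (camera, adjusted p = 0.0684). KRT19 and KRT18, 2 keratins of that list, had log2 fold changes of 0.72 and 0.49 (adjusted p = 0.299 and 0.550), and are named after their values were seen. The trophoblast list passed without Vehide replicate 2 (adjusted p = 0.00169), CGA-TMZ replicate 1 (0.0167) or CGA-TMZ replicate 2 (0.0360). The mesendoderm, mesoderm, neuroectoderm and fibroblast lists had adjusted p of 0.883, 0.572, 0.988 and 0.988.

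The number of genes called with CGA depended on the fit: 8 with all 3 groups, 333 (313 up, 20 down) with the CGA and Vehide libraries alone, and 262 with DESeq2. It was 529 without CGA-TMZ replicate 1, 522 without CGA-TMZ replicate 2, 23 without Vehide replicate 1 and 13 without CGA replicate 2, and 0 among genes of at least 10 CPM (edgeR, 864 at an unadjusted p under 0.05). The split also turned over: without Vehide replicate 2, 0 genes rose and 7 fell, and with the replicate block 0 rose and 2 fell. In the fit of those libraries alone, SLC25A1, HMGCS1, GAPDH, PGAM1 and NANOG had adjusted p of 0.00234, 0.00199, 0.00719, 0.00991 and 0.0166 (edgeR). Leaving out the CGA-TMZ group or 1 of its libraries kept all CGA and Vehide libraries. It took out of the shared spread the CGA-TMZ replicate pair, which differed most (chi-square per degree of freedom 89.6). The count of 8 thus depends on a group outside the comparison.

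**Figure D1:**
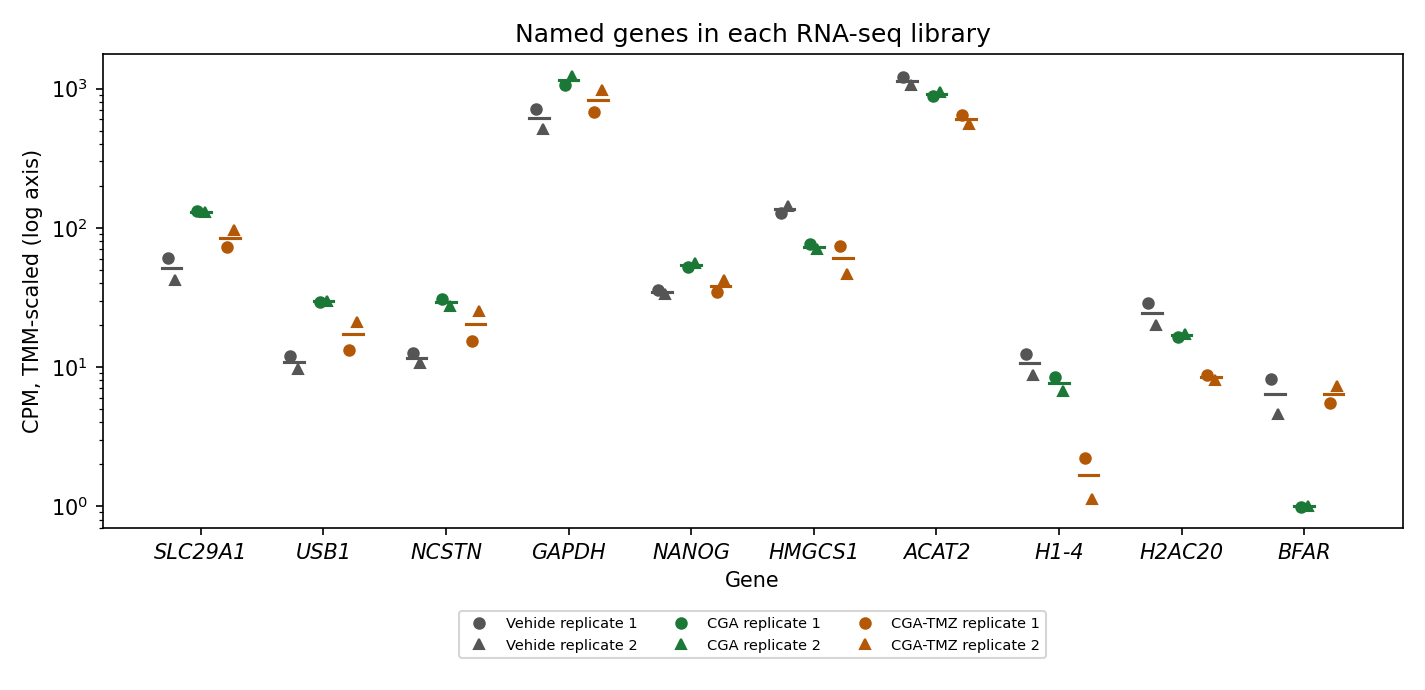
Level of 10 named genes in each of the 6 RNA-seq libraries, as TMM-scaled CPM on a log axis; circles are replicate 1, triangles replicate 2, and bars the mean of each group's 2 libraries. SLC29A1, USB1 and NCSTN lay higher in both CGA libraries than in both Vehide libraries, and H1-4 and H2AC20 were lowest in the CGA-TMZ libraries.

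The second comparison, CGA-TMZ against CGA, asked what the addition of TMZ changed on top of chlorogenic acid. The linker histone gene H1-4 fell from 7.63 ± 1.26 to 1.67 ± 0.788 CPM, a log2 fold change of -2.19 ± 0.32 (SE, adjusted p = 0.0387). BFAR rose from 51 counts in each CGA library to 284 and 420 (log2 fold change 2.68, adjusted p = 0.00640), and DHRS1 rose from 6 and 9 counts to 116 and 114 (log2 fold change 3.83, adjusted p = 0.00640). These were the 3 genes called by edgeR, and BFAR and DHRS1 are named after their values were seen, because their means lay under 10 CPM. H1-4 lost its call without CGA replicate 1 (adjusted p = 0.0505) and in the fit of the CGA and CGA-TMZ libraries alone (adjusted p = 0.242). The H1-4 gene spans 26156329 to 26157115 on chromosome 6.

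Replication-dependent histone genes passed as a lower list, with 25 of 34 estimates below 0 and a median log2 fold change of -0.15 (camera, adjusted p = 0.00909). With an estimated correlation of 0.00659, below the preset 0.01, the adjusted p was 0.952 (camera, unadjusted p = 0.0421). Over all genes 1 member fell, and 5 fell when adjusted over the list alone. The linker histone gene H1-1 was at 1.14 ± 0.278 CPM in CGA and 0.192 ± 0.0245 in CGA-TMZ (log2 fold change -2.56, adjusted p = 0.256). H1-3 was at 4.89 ± 0.390 and 1.96 ± 0.213 CPM (log2 fold change -1.32, adjusted p = 0.265). S phase genes did not pass, with 27 of 40 estimates below 0 (camera, adjusted p = 0.352). In CGA-TMZ against Vehide the S phase list had an adjusted p of 0.953 (camera). Histone genes of one type are close in sequence, so counts of single members are uncertain. How fully the amplification of mRNA captured transcripts of the histone list in each library was not tested. The list's adjusted p was 0.0811 without CGA replicate 1, 0.209 without CGA replicate 2 and 0.290 without CGA-TMZ replicate 2.

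Primed pluripotency genes passed as a lower list as well, with 19 of 29 estimates below 0 and a median of -0.16 (camera, adjusted p = 0.00909; adjusted p = 0.952 with an estimated correlation). None fell over all genes and 4 fell when adjusted over the list alone. ZFP42 (REX1) was at 94.3 ± 3.14 CPM in CGA and 55.7 ± 3.90 in CGA-TMZ (log2 fold change -0.76 ± 0.13, SE, adjusted p = 0.155). OTX2, a homeobox factor of primed cells, was at 117 ± 0.809 and 70.8 ± 6.11 CPM (adjusted p = 0.164). LIN28B, which blocks let-7 maturation, had a log2 fold change of -0.59 ± 0.13 (SE, adjusted p = 0.392). NANOG had a log2 fold change of -0.50 (adjusted p = 0.564), SOX2 one of 0.39 (adjusted p = 0.769) and POU5F1 one of -0.16 (adjusted p = 0.945), with the limit on its counts given above. The list passed in 1 of the 6 fits that left out a library. Its adjusted p was 0.0785 and 0.0877 without Vehide replicates 1 and 2, 0.112 and 0.198 without CGA replicates 1 and 2, and 0.403 without CGA-TMZ replicate 1.

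Ribosomal protein genes and oxidative phosphorylation genes passed as higher lists, with 76 of 82 and 57 of 69 estimates above 0 and medians of 0.18 and 0.16 (camera, adjusted p = 6.11e-11 and 1.08e-06; adjusted p = 0.952 for both with an estimated correlation). Of their members 0 passed the edgeR test, over all genes or adjusted over the list alone, with 5 ribosomal members above 0 and, for oxidative phosphorylation, 3 above and 1 below 0 at an unadjusted p under 0.05. NDUFB8 had a log2 fold change of 0.49 (adjusted p = 0.564), NDUFA2 had 0.29 (adjusted p = 0.735), and ATP5F1B went against the list with -0.47 (adjusted p = 0.662). RPL26, RPS20 and RPL26L1 had 0.42, 0.32 and 0.32 (adjusted p from 0.573 to 0.751). Without CGA replicate 1 both calls were lost: the adjusted p was 0.299 for ribosomal protein genes and 0.124 for oxidative phosphorylation genes, the latter at 0.125 without CGA-TMZ replicate 1.

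No fatty acid list passed: the adjusted p was 0.455 for mitochondrial beta-oxidation, 0.249 for synthesis and 0.559 for uptake and storage. Synthesis passed as a lower list without CGA-TMZ replicate 2 (adjusted p = 0.0445). So did glycolysis (adjusted p = 5.98e-04), which did not pass with all libraries (15 of 22 estimates below 0, adjusted p = 0.140). For beta-oxidation the median log2 fold change was 0.05 and the mean -0.01. CPT1A had a log2 fold change of 0.41 ± 0.30, HADHA -0.08 ± 0.15, HADHB -0.01 ± 0.13, ACAA2 -0.07 ± 0.14 and FASN -0.16 ± 0.30 (SE). The members with the smallest p were ACSL3 (0.26), ACAD10 (-0.77) and SLC25A20 (0.32) for beta-oxidation, with adjusted p from 0.779 to 0.853. For synthesis they were ACSS2 (-0.52), ELOVL1 (-0.58) and ELOVL3 (-1.15), with adjusted p from 0.764 to 0.783. For uptake and storage they were FABP3 (-0.46), LPIN1 (0.45) and LIPA (-0.29), with adjusted p from 0.623 to 0.776. The uptake and storage list passed the test for change in either direction (fry, mixed adjusted p = 3.63e-06), which does not compare it with other genes. The count of 3 called genes was 338 without CGA-TMZ replicate 2, 36 without CGA-TMZ replicate 1, 9 without CGA replicate 1, 7 without CGA replicate 2, and 26 with DESeq2.

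**Figure D2:**
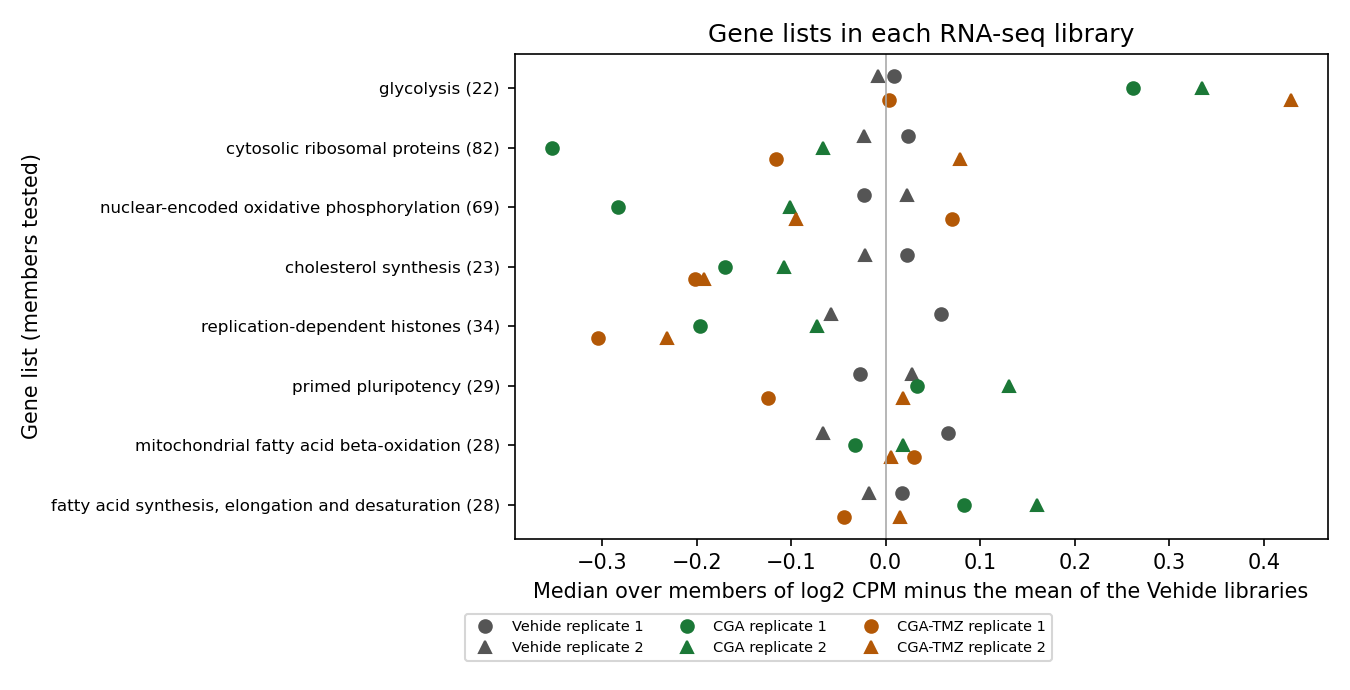
Median over the tested members of each gene list of the log2 CPM in a library minus the mean of the Vehide libraries; circles are replicate 1 and triangles replicate 2. Both CGA libraries lay above 0 for glycolysis, at 0.26 and 0.33, while the CGA-TMZ libraries lay at 0.00 and 0.43, and CGA replicate 1 stood apart for ribosomal protein genes at -0.35.

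Whether TMZ moved the CGA response back was asked of the genes called in both comparisons. BFAR and DHRS1 were called in both with opposite sign, and 0 genes were called in both with the same sign. The count expected of independent lists was 5.74e-04. In 50 simulations of unchanged groups that shared the CGA libraries, the mean count was 0.780 and the highest 4. Over 19149 genes the correlation of the log2 fold changes was -0.440, against a simulated mean of -0.507 ± 0.0125 (SD). The covariance was -0.188 against a simulated -0.146 ± 0.00565 (SD), a difference of -0.0418. The simulation drew genes independently and with the same spread per gene in all groups, though replicates differed most in CGA-TMZ. These differences therefore do not decide whether TMZ moved the response back. With a different CGA library in each comparison, a test added after seeing the data, the fold changes of the 2 comparisons shared no library. Each fit still took its spread from the Vehide and CGA-TMZ pairs, so the calls in the 2 comparisons are not independent. BFAR and DHRS1 were then called in both with opposite sign and 1 gene with the same sign, with CGA replicate 1 against Vehide and replicate 2 against CGA-TMZ. With the replicates exchanged BFAR alone was called in both. The correlation across 20427 genes, which are not independent replicates, was -0.0740 and -0.0572 in these fits. The count of 2 genes was 145 without CGA-TMZ replicate 2, 7 without CGA-TMZ replicate 1, 5 without either CGA library and 1 without Vehide replicate 2.

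The third comparison, CGA-TMZ against Vehide, asked what differed from the vehicle when both were given. At an unadjusted p under 0.05 (edgeR) 738 genes lay higher and 888 lower. Without CGA-TMZ replicate 1 more of the called genes rose than fell. With all libraries, of 17 genes called, 16 fell. The 1 that rose is annotated in a pseudoautosomal region of the Y chromosome and is not named under the rule. Histone genes were among those that fell, with the limits on their counts given above. H2AC14 fell from 16.7 ± 3.55 to 4.65 ± 1.84 CPM (log2 fold change -1.84 ± 0.27, SE, adjusted p = 0.0167). H2AC20 fell from 24.4 ± 6.17 to 8.42 ± 0.439 CPM (log2 fold change -1.54 ± 0.20, SE, adjusted p = 0.00700). H1-4, H1-3 and H1-5 fell too, with log2 fold changes of -2.67, -1.88 and -1.33, and are named after their values were seen. H2AC20, H2AC14 and H1-3 lost their calls without Vehide replicate 1 (adjusted p of 0.0818, 0.125 and 0.127), and H1-5 without either Vehide library or in the fit of the 2 groups alone (0.0951). Replication-dependent histones as a list had a median of -0.21 and 24 of 34 estimates below 0 (camera, adjusted p = 2.35e-05). With an estimated correlation of 0.0130, near the preset 0.01, the list had an adjusted p of 0.286 (camera, unadjusted p = 0.0173). Of its members 3 fell over all genes and 5 when adjusted over the list alone; H2AC14 and H2AC20 were not on the list.

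Cholesterol synthesis genes were the other list that passed, with 18 of 23 estimates below 0 and a median of -0.18 (camera, adjusted p = 4.92e-05). With an estimated correlation of -0.0138, below the preset 0.01, the adjusted p was 0.286 (camera, unadjusted p = 0.0141). HMGCS1 fell from 136 ± 10.8 to 60.2 ± 19.2 CPM (log2 fold change -1.17 ± 0.18, SE, adjusted p = 0.0302). ACAT2, the thiolase that makes acetoacetyl-CoA at the start of the pathway, fell from 1217 and 1068 to 643 and 557 CPM (log2 fold change -0.93 ± 0.15, SE, adjusted p = 0.0322). These were the 2 members called, over all genes and over the list alone. In the CGA libraries ACAT2 was at 882 and 940 CPM, between the other groups; ACAT2 is named after its values were seen. HMGCS1 and ACAT2 lost their calls without either Vehide library (adjusted p up to 0.373 and 0.355) and in the fit of the CGA-TMZ and Vehide libraries alone (0.0699 and 0.146), and the list's adjusted p was 0.0560 without Vehide replicate 1.

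The zinc finger gene ZNF708 fell from 41.1 ± 0.620 to 18.6 ± 4.98 CPM (adjusted p = 0.0302), and HNRNPA3, an RNA-binding protein gene with several processed pseudogenes, fell from 167 and 180 to 98.8 and 76.2 CPM (log2 fold change -0.99 ± 0.15, SE, adjusted p = 0.0218). Both lost their calls without either Vehide library (adjusted p up to 0.209 and 0.355) and in the fit of the 2 groups alone (0.0699 for both). The fatty acid lists did not pass, with adjusted p of 0.624 for beta-oxidation and 0.887 for both synthesis and uptake and storage (the last had a fry mixed adjusted p of 0.0399), nor did ribosomal protein genes (0.871) or oxidative phosphorylation genes (0.887). The remaining calls included MTX1P1, IBTK, CCNK, ACTR2, METTL16 and MYSM1, with log2 fold changes from -0.83 for MYSM1 to -4.95 for MTX1P1, and these are named after their values were seen. MTX1P1, H1-4 and IBTK were the 3 of the 16 that passed in all 6 fits that left out a library. The count of 17 was 644 without CGA-TMZ replicate 1, 55 without CGA-TMZ replicate 2, 9 without Vehide replicate 1, 74 with DESeq2, 8 with upper quartile factors and 0 among genes of at least 10 CPM (edgeR, 769 at an unadjusted p under 0.05).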

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

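The length correction, the list tests on 2 groups and the test with a different CGA library in each comparison were chosen after seeing the data. Of 1239 alternative values for 68 named gene fold changes, 65 gained a call and 55 lost one. The others kept their side of the threshold, 32 of them uncalled and moved by more than their standard error, and 0 called values reversed. DESeq2 called 262, 26 and 74 genes in CGA against Vehide, CGA-TMZ against CGA and CGA-TMZ against Vehide, in place of 8, 3 and 17, and 4 moved back in place of 2. Without the low-count filter these were 334, 35, 106 and 9. With a mean of at least 10 CPM edgeR called 0 in each comparison and 0 moved back, from 864, 596 and 769 genes at an unadjusted p under 0.05. Limma on log2 FPKM also called 0 in each and 0 moved back, with 1161, 821 and 753 at an unadjusted p under 0.05 with a pseudocount of 1, and 1152, 820 and 765 with 0.1. With limma-voom the first count was 13 and 1 gene moved back. With only the 2 groups compared the counts were 333 for CGA against Vehide and 9 for CGA-TMZ against Vehide. CGA-TMZ against Vehide gave 11 genes with median-of-ratios factors, 8 with upper quartile factors and 10 with a 2-fold minimum. With the length trend removed the counts were 8, 3 and 14. With a different CGA library in each comparison 2 or 1 genes moved back. Leaving out 1 library gave 7 to 529, 4 to 338 and 9 to 644 genes, and 1 to 145 moved back. The highest of these came without a CGA-TMZ library. In CGA against Vehide, leaving out a CGA-TMZ library or that group took the CGA-TMZ replicate pair out of the shared spread. Beyond this, the cause was not tested for any of these differences, those from leaving out 1 library included. Of the genes called, 2 of 8, 2 of 3 and 3 of the 16 that fell passed in all 6 such fits, and all kept their sign.

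The samples share a replicate number only: deviations of same-numbered libraries from their group means correlated at 0.00410 (Vehide and CGA), -0.0437 (Vehide and CGA-TMZ) and 0.0177 (CGA and CGA-TMZ). With the replicate block 2, 4 and 8 genes were called and 1 moved back.

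Among lists, 4, 4 and 2 were called, and 0 with an estimated correlation (camera, 1, 1 and 2 at an unadjusted p under 0.05) or with fry (1, 2 and 3). The test with an estimated correlation rests on 3 residual degrees of freedom, so 0 calls there need not mean correlation within lists. In the test for either direction fry called 0, 4 and 3. With a mean of at least 10 CPM 1 list was called in CGA-TMZ against Vehide, where the histone list no longer had enough members. Leaving out 1 library gave 1 to 6, 0 to 6 and 2 to 7 lists. Small changes were often missed: at 2 libraries per group the self-test recovered 16% of 1.5-fold changes in CGA against Vehide.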

Other observations

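The tests of explanations in this part were chosen after the results were seen. Outside the comparisons above, MALAT1, a nuclear long non-coding RNA, was at 757 and 1021 CPM in Vehide, 551 and 455 in CGA and 638 and 431 in CGA-TMZ. Its log2 fold change in CGA against Vehide was -0.82 (edgeR, adjusted p = 0.158), and its list of nuclear-retained long RNAs did not pass (camera, adjusted p = 0.112). H1-2, a linker histone gene, was at 56.8 and 36.7 CPM in Vehide, 30.3 and 27.3 in CGA and 14.2 and 6.70 in CGA-TMZ (log2 fold change -2.16 in CGA-TMZ against Vehide, adjusted p = 0.170). G2/M phase genes had 29 of 42 estimates below 0 in CGA-TMZ against Vehide, without passing (camera, adjusted p = 0.0579). No other list passed in any comparison: the smallest adjusted p of a list not called was 0.0684 in CGA against Vehide and 0.140 in CGA-TMZ against CGA. Naive pluripotency genes had a median log2 fold change of -0.28 over 10 tested members in CGA-TMZ against Vehide (camera, adjusted p = 0.203).

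The CGA-TMZ libraries differed along the genes that rose with CGA (of the 20 that fell, 55% lay nearer the CGA mean in each), and were also the lowest and highest of the 6 in mitochondrially encoded RNA (3.91% and 5.65%) and in genes at 1 CPM (12133 and 12595). For the 313 genes that rose with CGA in the fit of the 2 groups, CGA-TMZ replicate 1 lay near Vehide and replicate 2 near CGA, with medians of 0.16 and 0.77 above the Vehide mean against 0.86 and 0.93 in CGA (log2). Across 6675 genes at 10 CPM or more, which are not independent replicates, replicate 2 minus 1 correlated at 0.431 with CGA minus Vehide, and at 0.109 over all 19149 genes tested. Whether replicate 2 was a mislabelled CGA library stays open. A set of 54 genes was chosen from CGA-TMZ replicate 1 against Vehide, among those in the fit of all libraries. Replicate 2 lay beyond both CGA libraries in 66.7% of them. Its median shift towards replicate 1 was 0.78, against 0.36 and 0.33 in CGA (log2 from the Vehide mean). Many exchangeable CGA libraries would average 33.3%, but genes can vary together, so 1 library may lie far from that. Over whole libraries the values go the other way. Replicate 2 differed least from CGA replicate 2 (chi-square per degree of freedom 31.7) and replicate 1 from Vehide replicate 2 (39.1), against 89.6 between the CGA-TMZ libraries. By Spearman correlation replicate 2 was also nearest CGA replicate 2 (0.975), but replicate 1 was nearest Vehide replicate 1 (0.974). Between the CGA-TMZ libraries this correlation was 0.972. The label of replicate 1 was not tested. A trend on gene length and depth are argued against as whole causes, since the gap of 0.61 was 0.592 with the trend removed and 0.614 with all libraries thinned to the depth of the smallest, while a response to TMZ that varies between cultures, a difference in RNA quality and GC content may account for it and were not tested.

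Of the 333 genes called with CGA in the fit of the 2 groups, 94.0% rose, 313 against 20. Scaling between libraries stays open: upper quartile factors gave 204 against 22 (90.3%), but the other factors moved the median of all genes by at most 0.04, against a median of 0.88 in the risen genes, too little to decide. A trend on gene length is argued against as the whole cause too, since 93.8% of 436 calls rose with the trend removed and 312 of the 313 were called again. GC content could not be tested with no genome in hand, so an effect of sequence composition on amplification may account for part or all of the rise, and a response to CGA stays open as well.

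Genes of the major histocompatibility complex on chromosome 6 (hg38, rows from 28503296 to 33453689) were counted near 0: 80% of 70 protein-coding rows had a mean under 20 counts, TUBB (7.33), CSNK2B (0.500) and DDX39B (0.333) among them, against 27.0% elsewhere on the chromosome. A candidate explanation is loss of reads that also match the alternative haplotype contigs of the assembly, and 17q21.31 (chromosome 17, rows from 45393902 to 46757679), which has such contigs too, had 100% of 9 rows under 20 counts against 37.8% elsewhere (Fisher's exact test, two-sided, p = 1.68e-04). There KANSL1 held a mean of 2.67 counts and NSF 2.17, while GOSR2 beside the region held 1752. A donor haplotype unlike the reference is argued against as the whole cause. The polymorphic classical HLA genes had a median count 66.6 times that of the other genes of the complex, at 44.4 against 0.667. They ranged from a mean of 7.67 counts in HLA-B to 1053 in HLA-DQB1, so a loss of reads in single genes is not excluded. Levels of POU5F1, RPS18 and other genes of these regions carry this limit, and the sequence of the contigs was not examined.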
